A study of Mus musculus with 2 samples.

How the data were processed

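The series holds 2 total RNA libraries of gastrocnemius from 10 day old female B6CASTF1/J mice, per the labels, with ribosomal RNA reduced, stranded library preparation and ERCC spike-ins. RNA was purified with a Norgen animal tissue kit, per the labels. Each library has a gene table and a transcript table with the columns of RSEM and a transcript table with the columns of kallisto. The tools and versions that made them are not given in the sources used here, so the tables are called RSEM-format and kallisto-format. The genome build was mm10 with the GENCODE M21 annotation, per the text files deposited beside the tables. The deposited gene and transcript tables give expected counts and the kallisto-format tables estimated counts, in which reads that match several transcripts are divided by a model, per the file headers. TPM and posterior mean TPM in the deposited tables are transcript abundances scaled by effective length to a fixed total per library and include the spike-ins. The percent of each gene's abundance held by a transcript is a column of the deposited RSEM-format transcript tables, and lengths are in nucleotides.

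Each RSEM-format gene table has 81881 rows: 55536 Ensembl genes, all matched to GENCODE M21 for symbol, class and coordinates, 26248 rows with a number and no name, and 97 spike-in rows that include phiX. Rows that name no gene held 1.38e-05% of counts in replicate 1 and 5.00e-06% in replicate 2 and were left out, as were spike-ins except where named. Spike-ins took 0.720% and 0.798% of counts. The kallisto-format tables hold 35532610 and 39103802 estimated counts. Kallisto-format values were summed per gene over 141767 shared transcripts. Where a symbol has several gene identifiers, as Aldoa, Atp5o and Rmrp do, the one with the most counts was used in lists, and the erythroid gene Ahsp was not matched by symbol. The labels give 1 group with biological replicate numbers 1 and 2 from separate biosamples; they do not state that each came from 1 animal.

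Lists of genes, isoform pairs, the measures reported and most of the other settings tried were set before the data were examined; the closing paragraphs name the tests, settings and limits chosen later. A gene was called detected at TPM 1 or more in both libraries. Shares are percent of TPM over named genes. The log2 ratio of an isoform pair was taken within each library, and its direction was called where both libraries had the same sign and the mean exceeded 1 SD. Expected counts were rounded to whole numbers, and replicate ratios were TMM-scaled log2 CPM with a prior count of 0.5 in edgeR 4.0.16 under R 4.3.3. The dispersion was the common dispersion of edgeR's model over genes with a mean count of at least 10. Size factors of DESeq2 1.42.0, library totals and spike-in totals were alternatives. A list's median ratio was set against 10000 random lists of the same size, matched in 20 bins of mean count, over genes with a mean count of at least 20 and lists with at least 5 such members, and called outside at percentiles up to 2.5 or from 97.5. This percentile describes these 2 libraries and is not a test of a condition. Log2 ratios between the tools used a pseudocount of 0.01. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

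The genes named in the text follow a fixed rule: the 20 highest by mean TPM, every sarcomeric myosin heavy chain, the leading 3 of each list with members at 0 of other-cell lists, every isoform pair, the 10 nuclear protein coding genes with the largest ratio in each direction between libraries at a mean count of at least 100, the 10 in each direction between tools, the isoform genes, and the 5 highest of each noncoding class. Members outside the leading 3 of a list that the text names, such as Pax7, Ryr1, Myod1, Mstn, Slc4a1 and Neat1, and the single genes of the closing paragraphs, were chosen after their values were seen. Single genes that the rule names or that belong to the lists may be left out of the text and are not reported here.

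The replicate comparison was tested on simulated data drawn from the real means and library sizes with a coefficient of variation of 0.15 and 200 changed genes. The estimate was 0.150, 46% of genes changed 2-fold and 94% of those changed 4-fold passed the 2-fold limit, and 0.182% of unchanged genes did, over 11746 genes with a mean count of at least 100. The list percentile was tested on simulated lists of 15 genes, of which 3.5% lay outside with no shift and 100% with a log2 shift of 0.5. Alternatives covered scaling, filters, pseudocounts, fold limits, the kallisto-format tables and leaving out each replicate.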

Results

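Total RNA of the gastrocnemius, the large calf muscle, was sequenced from female mice at postnatal day 10. The animals were F1 hybrids of the C57BL/6J and CAST/EiJ strains, and the series holds 1 group of 2 libraries, labelled biological replicates 1 and 2 and made from 300 ng of RNA each. Ribosomal RNA was reduced before library preparation and ERCC spike-in RNAs, synthetic transcripts of known sequence, were added. The tables hold 35925081 expected counts for replicate 1 and 39969380 for replicate 2. The design has no second group, so the questions are which genes and transcript forms the muscle expressed at this age, and how far the 2 libraries differed. No test of 1 library against the other is possible, since each side would hold 1 library. For values taken within each library, the smallest two-sided sign-flip p over 2 libraries is 0.5, so no p is given. Values are given as mean ± SD with n = 2 or per library. Coordinates are those of mm10 in the GENCODE M21 annotation.

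Transcripts of fast contractile genes far outweighed those of slow ones. Acta1, skeletal muscle alpha actin (chromosome 8, 123891769 to 123894751), was the most abundant nuclear protein coding transcript at a TPM of 24341 ± 2768 (SD, n = 2). It was followed by Mylpf, the fast regulatory light chain, at 21636 ± 1753, by Myl1, the fast alkali light chain, at 13023 ± 1618, and by Ckm, muscle creatine kinase, at 11020 ± 1517. The 20 highest nuclear protein coding genes together held 31.4% ± 2.79 of nuclear protein coding TPM (SD, n = 2). All 14 genes of the fast contractile list were detected, at TPM 1 or more in both libraries, and held 8.51% ± 1.03 of all gene TPM. The 12 slow contractile genes were also all detected and held 0.215% ± 0.0126. Kallisto-format TPM gave 14.0% and 0.361% for these 2 lists.

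Among the 9 sarcomeric myosin heavy chain genes, Myh4, which encodes the fast type 2B chain, led with 69.3% ± 6.23 of their TPM (SD, n = 2). Myh4 lies on chromosome 11 from 67238029 to 67260446 in a cluster with Myh1, Myh2, Myh3, Myh8 and Myh13. Its TPM was 7652 in replicate 1 and 9946 in replicate 2. Myh1, the type 2X chain, held 15.9% ± 2.00. Myh8, the perinatal chain, held 8.32% ± 3.51, with 10.8% in replicate 1 and 5.84% in replicate 2, so that its share in 1 library was over 1.5 times that in the other. Myh2, the type 2A chain, held 4.01% ± 0.407. The slow chain Myh7 held 1.78% ± 0.112, the cardiac alpha chain Myh6 0.339% ± 0.0884, and the embryonic chain Myh3 0.310% ± 0.112. Myh13 and Myh7b were near the detection level, at TPM 1.75 ± 0.106 and 1.06 ± 0.0778. The order Myh4, Myh1, Myh8, Myh2, Myh7 held in both libraries. Myh1 held 24.0% in the kallisto-format tables, 1.5 times its main share, so its level depends on the tool. Myh6 held 0.128% by kallisto-format TPM and 0.0873% by expected counts, against 0.291% and 0.315% for Myh3. The order of Myh6 and Myh3 therefore depends on the measure. Myh7 held 1.24% and 1.26% by these measures.

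**Figure D1:**
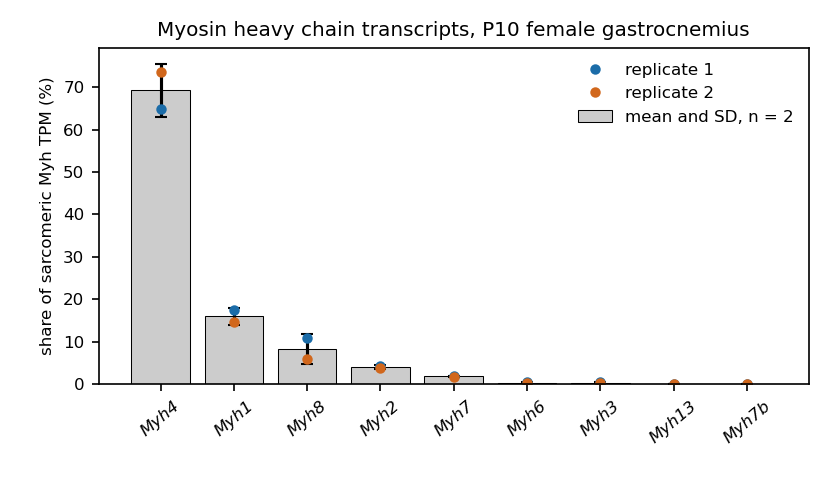
Share of sarcomeric myosin heavy chain TPM (y axis, percent) for the 9 genes (x axis); bars are means, error bars SD of n = 2, and points the 2 libraries. Myh4 held 64.9% in replicate 1 and 73.7% in replicate 2.

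The gene named second was the higher one in each of the 28 pairs of developmental, fibre type or tissue isoforms, in both libraries. In most pairs the gene named first is the embryonic, slow, cardiac or general form; Myh1 and Myh2 over Myh4 set fast chains against each other, and Myh3 over Myh8 the embryonic against the perinatal chain. In 22 of the 28 pairs the second gene was at least 4-fold higher in both libraries. Myl4, the embryonic and atrial light chain, lay furthest below its partner Myl1, at a log2 ratio of -9.37 ± 0.38 (SD, n = 2). Ckb, the brain creatine kinase, lay below Ckm at -8.97 ± 0.86, and Tnnt2, cardiac troponin T, below Tnnt3 at -8.59 ± 0.34. The slow troponins were each far below the fast ones, with Tnni1 over Tnni2 at -5.89 ± 0.24, Tnnc1 over Tnnc2 at -5.63 ± 0.11 and Tnnt1 over Tnnt3 at -5.60 ± 0.18. For the calcium pumps, Atp2a2 over Atp2a1 stood at -6.09 ± 0.18. Chrne, the adult acetylcholine receptor subunit, was above Chrng, the fetal one, with Chrng over Chrne at -3.21 ± 0.45 and TPMs of 14.6 ± 1.26 and 1.59 ± 0.354. Cardiac actin, Actc1, was still abundant at a TPM of 1980 ± 861, and Actc1 over Acta1 stood at -3.69 ± 0.48. The perinatal Myh8 over Myh4 stood at -3.12 ± 0.76, and Myh3 over Myh8 at -4.73 ± 0.09. The metabolic pairs ranged widely: Pgam1 over Pgam2 was -6.39 ± 0.36, Slc2a1 over Slc2a4 -4.66 ± 0.06, Ldhb over Ldha -4.49 ± 0.07, Eno1 over Eno3 -3.51 ± 0.05, Cox8a over Cox8b -1.88 ± 0.03 and Hk1 over Hk2 -1.65 ± 0.70. Cox7a2 over Cox7a1 was -0.58 ± 0.23 and turned to 0.31 with kallisto-format TPM and to 0.22 as a ratio of expected counts.

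**Figure D2:**
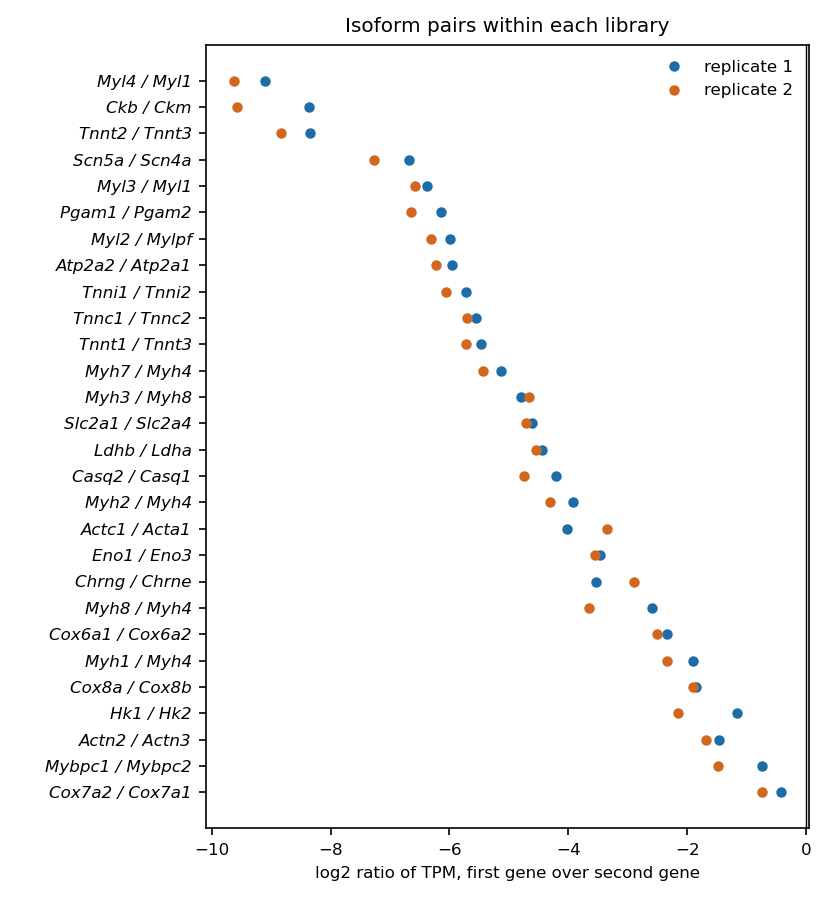
Log2 ratio of TPM of the first over the second gene (x axis) for 28 isoform pairs (y axis), with 1 point per library. All points lie below 0, from -9.63 for Myl4 over Myl1 in replicate 2 to -0.42 for Cox7a2 over Cox7a1 in replicate 1.

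Genes of the sarcomere scaffold, of calcium handling and of fuel use were expressed throughout. All 19 scaffold genes were detected, led by Ttn, the giant spring protein titin, at TPM 2060 ± 96.3, Neb, nebulin, at 1714 ± 123 and Des, desmin, at 708 ± 60.9 (SD, n = 2). All 20 excitation-contraction coupling genes were detected, led by Trdn, Srl and Sypl2, with the release channel Ryr1 at 322 ± 0.679 and its voltage sensor Cacna1s at 257 ± 13.5. The 25 glycolysis and glycogen genes held 1.86% ± 0.190 of TPM, with Aldoa at 4104 ± 518, Gapdh at 3572 ± 333 and Eno3 at 2430 ± 184. The 27 nuclear oxidative phosphorylation genes held 0.961% ± 0.101, led by Atp5b, Atp5a1 and Cox4i1. The 13 mitochondrially encoded protein genes held 3.56% ± 0.121, led by mt-Co1 at 8636 ± 479. Values of mt-Atp6, mt-Co2 and mt-Co3 are uncertain, since RSEM-format and kallisto-format TPMs were 1808 against 11112, 60.2 against 607 and 930 against 1799. So are those of mt-Nd4l, at 2611 against 30.2, and mt-Atp8, at 3429 against 0, and of Gm10925, a pseudogene on chromosome 1, at 8688 against 794. Beside Gm10925 lie the pseudogenes Gm28661, Gm28437 and Gm29216, at RSEM-format TPMs of 10781, 6920 and 3485. How reads were divided between these pseudogenes and the mitochondrial genes was not tested. The share of the mitochondrially encoded list and its leading gene are therefore uncertain too. Among the 21 fatty acid genes, Fabp3, Etfb and Acadl led, and the list held 0.179% ± 0.000352. All 18 dystrophin complex genes were detected, with Dag1 at 128 ± 11.9, and so were all 15 neuromuscular junction genes, with Chrnb1 at 52.2 ± 4.09 and Musk at 11.4 ± 1.70.

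Regulators of muscle formation were present beside growth and imprinted genes. All 23 myogenic regulators were detected, led by Nfix at TPM 283 ± 25.5 and Mef2c at 211 ± 0.530. Myog stood at 59.7 ± 0.226, Myf6 at 54.0 ± 10.1, Myod1 at 20.1 in replicate 1 and 21.9 in replicate 2, and Myf5 at 4.02 ± 0.191 (SD, n = 2). The stem cell factor Pax7 was detected at 4.43 ± 0.799, while Pax3 was at 0.0350 ± 0.00707, below the detection level. Of 14 satellite cell markers, 12 were detected. Among imprinted genes, which are expressed from 1 parental copy, 23 of 25 were detected; H19 stood at 7049 ± 237 and Igf2, a fetal growth factor, at 2685 ± 351. Igf2 was far above Igf1, at 43.6 ± 2.09, and Mstn, myostatin, stood at 27.7 ± 0.191. The tables hold no allele-specific values, so parental expression was not analysed here. All 20 cell cycle genes were detected at low levels, with Mki67 at 13.8 ± 3.67 and Top2a at 17.3 ± 3.10.

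Markers of other cell types of a whole muscle were detected as well. The 23 fibroblast and matrix genes held 0.869% ± 0.266 of TPM, with Col1a1 at 2714 ± 1171 (3542 in replicate 1 and 1887 in replicate 2) and Col3a1 at 1447 ± 241 (SD, n = 2). All 11 endothelial, 10 tendon, 10 pericyte and smooth muscle, and 11 macrophage markers were detected, with Cdh5 at 70.2 ± 5.64, Fmod at 91.4 ± 9.21, Rgs5 at 89.0 ± 4.75 and Lyz2 at 18.9 ± 5.05. Of 12 Schwann cell genes 11 were detected. The globins Hba-a1 and Hbb-bs stood at 558 ± 81.4 and 553 ± 120. Of 10 neuron and axon genes, Uchl1 and Stmn2 were detected in both libraries, and Chat was at 0 counts in both. Of 8 keratinocyte markers, Trp63, Krt10 and Krtdap were detected, and of 13 lymphocyte and granulocyte markers, Ptprc. The brown fat gene Ucp1, the T and NK cell gene Nkg7 and the interferon gene Ifi44 were at 0 counts in both libraries, which allows up to 0.0841 CPM (counts scaled to library size) in replicate 1 and 0.0757 in replicate 2. Such limits cover counting error only. Posterior limb genes Hoxc10 and Hoxa10 stood at 23.6 ± 1.22 and 12.9 ± 1.00, Tbx4 at 1.74 ± 0.311 and the forelimb gene Tbx5 at 0.0200 ± 0.0141. Xist, the RNA of the inactive X chromosome, stood at 61.4 in replicate 1 and 34.1 in replicate 2, and the Y-linked genes Ddx3y and Usp9y were at 0 counts in both. By the kallisto-format tables the Y-linked Uty stood at 1.07 and Gm47283, placed on the Y chromosome, at 67.1, against 0.00500 and 0 by RSEM, so these 2 values are uncertain.

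Of 55536 named genes, 12562 were detected at TPM 1 or more in both libraries, 11527 of them protein coding, and 66 reached TPM 1000 in both. By annotated class, nuclear protein coding genes held 46.5% ± 0.684 of gene TPM, small noncoding RNAs 34.6% ± 1.14, mitochondrial genes 11.3% ± 0.812, pseudogenes 4.71% ± 0.165 and long noncoding RNAs 2.87% ± 0.516 (SD, n = 2). The pseudogene share includes Gm28661, Gm10925, Gm28437 and Gm29216, named above, so it and the mitochondrial share are uncertain. The small noncoding share came mainly from Rn7s1 and Rn7s2, entries for the signal recognition particle RNA listed at the same TPM of 139314 each, so their single values are uncertain, and from Rn7sk, the RNA that holds back the elongation factor P-TEFb, at 27122 ± 3137. In expected counts small noncoding RNAs held 5.32% and nuclear protein coding genes 77.8%, and in kallisto-format TPM 0.0285% and 75.6%, so TPMs of coding genes are scaled down in the main tables by these short RNAs. Among genes annotated as long noncoding the highest were Gm26917 at 9459 ± 1038 (chromosome 17, 39843013 to 39846341), H19, Gm42418 at 2459 ± 515 and Malat1 at 1702 ± 752. Gm26917 and Gm42418 lie next to each other on chromosome 17. Which RNA their reads come from was not tested, so the long noncoding share is uncertain. Muscle microRNA host Mir133a-1hg stood at 27.0 ± 11.8 and Myhas, antisense within the myosin cluster, at 17.4 in both libraries. The 94 ribosomal protein genes held 2.81% ± 0.0786, led by Rpl41, and the 67 histone genes of the replication-dependent clusters 0.404% ± 0.0447.

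Among nuclear protein coding genes, the largest fold differences between the 2 libraries were mostly in genes of bone and blood-forming cells. Across 13780 genes at TPM 1 or more in either library, log2(TPM + 1) had a Pearson r of 0.978 and a Spearman rho of 0.975; genes are not independent replicates. The biological coefficient of variation was 0.192 over 16790 genes, against 0.0258 over 48 spike-ins, and the chi-square per degree of freedom was 48.6 over the same genes and 3.06 over the spike-ins, so the tables do not hold 1 library given under 2 names. The ratios below are TMM-scaled; library totals and spike-ins would lower the log2 ratio of replicate 2 over replicate 1 by 0.24 and 0.39 for every gene.

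Of 11760 genes with a mean count of at least 100, 120 differed by at least 2-fold, 95 higher in replicate 1 and 25 higher in replicate 2. With library totals the split was 172 and 17, and with spike-in scaling 273 and 13; since each of the 3 other scalings lowers every ratio, the first set could only stay and the second shrank to 13 of 25. With kallisto-format counts 82 of the 95 and 20 of the 25 passed, and 8 of the 25 passed in all of these settings. By class, 60 of the 95 were nuclear protein coding and 31 long noncoding, against 18 and 1 of the 25. Without listed bone and marrow genes 102 of the 120 remained. Among nuclear protein coding genes, the 10 with the largest excess in replicate 1 were led by Ibsp, bone sialoprotein, with 1900 counts against 0 (at least 595-fold higher against a floor of 3 counts per library), Bglap, osteocalcin, with 737 against 0 (at least 231-fold), and Bglap3, with 245 against 0 (at least 76.8-fold). They were followed by Ngp, a neutrophil granule gene (219 against 0, at least 68.6-fold), Mmp13, a collagenase (1527 against 5), Spp1, osteopontin (3876 against 24, 149-fold), the granulocyte gene S100a8 (205 against 1), Ahsg, fetuin (279 against 4), Acp5, the acid phosphatase of osteoclasts (1937 against 35), and Slc13a5, a citrate carrier (346 against 6). In the other direction differences were smaller. They were led by Fam220a at a log2 ratio of 2.47, which was 0.04 by the kallisto-format tables, and by Slc25a25 at 1.77, Chac1 at 1.64, Nnt at 1.54 (0.27 by kallisto), Lrrc30 at 1.45, the immediate early gene Nr4a1 at 1.43, the kinase gene Sgk1 at 1.43, Otud1 at 1.39, Mybph at 1.30 and the clock gene Per1 at 1.29.

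**Figure D3:**
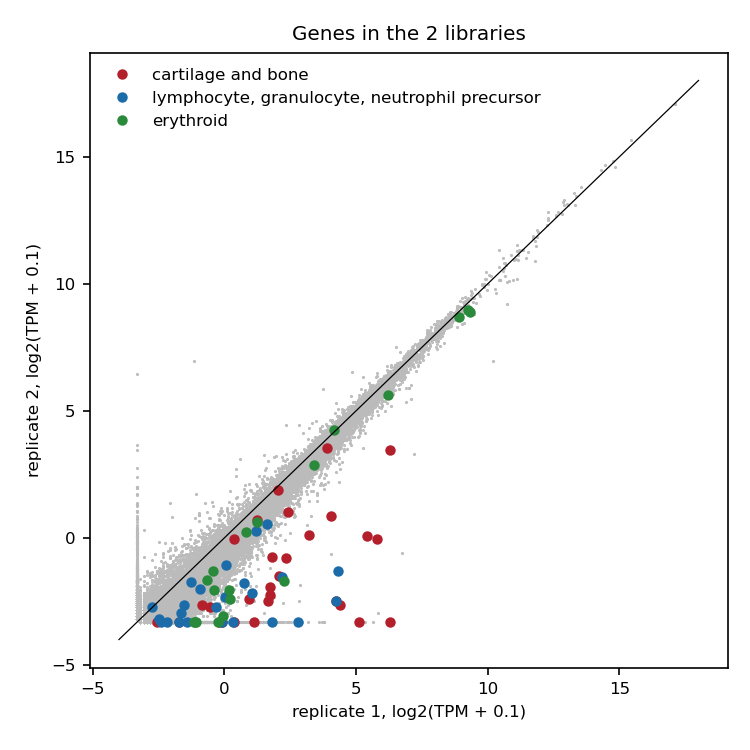
Log2(TPM + 0.1) of each gene in replicate 1 (x axis) and replicate 2 (y axis); grey points are genes above 0 in either library, coloured points 3 sets of lineage genes, and the line marks equality. Ibsp stood at TPM 34.2 in replicate 1 and 0 in replicate 2, on the lower edge.

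Of 37 gene lists with at least 5 members at a mean count of 20, 14 had a median log2 ratio outside the central 95% of matched random lists, 10 on the low side and 4 on the high side. Of 37 random lists 1.85 would lie outside. Random lists hold genes drawn singly, while the gene lists share members and their genes can move together, so 14 against 1.85 is not a test. Cartilage and bone markers were lower in replicate 2 in 8 of 8 members, at a median of -3.91. Lymphocyte and granulocyte markers were lower in 6 of 7, at -5.59 (-5.41 with members at 0 set to 3 counts), with S100a9 at 229 and 4 counts. Adipocyte markers stood at -1.24, with Plin1 at 331 and 91 counts. Of the fibroblast and matrix genes 20 of 23 were lower, at -0.15, including Col1a1 at -0.63 and Col1a2 at -0.59, while Col3a1 was at -0.08 and Dcn at 0.13; with spike-in scaling all 23 were lower. Abundant noncoding RNAs stood at -0.63, with Meg3 at -1.37, Malat1 at -0.73 and Neat1 at -0.63 against mt-Rnr2 at 0.50. Erythroid, macrophage, cell cycle, imprinted, and embryonic and neonatal lists also lay low, at -0.29, -0.20, -0.13, -0.12 and -0.05. The macrophage call, with 6 members lower and 5 higher (11 and 0 with spike-in scaling), was lost at a mean count of 100 and with kallisto-format counts, and the embryonic and neonatal call, with 6 lower and 4 higher (9 and 1), against unmatched lists. The erythroid list parted, with Slc4a1 at -3.92 and Hba-a1 at -0.03. On the high side, all 14 fast contractile genes (median 0.52), all 27 nuclear oxidative phosphorylation genes (0.49), 23 of 25 glycolysis and glycogen genes (0.47) and 18 of 20 excitation-contraction coupling genes (0.38) were higher in replicate 2. With spike-in scaling these counts were 11, 22, 18 and 10, and the last median was -0.01. All members were also higher in replicate 2 in lists whose medians lay inside the random range: 12 slow contractile, 13 mitochondrially encoded, 18 dystrophin complex, 19 scaffold and 21 fatty acid genes; with spike-in scaling 0, 3, 4, 7 and 2 of them were. The perinatal genes did not move as 1 set, since Myh8 stood at -0.41 and Actc1 at 1.19.

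**Figure D4:**
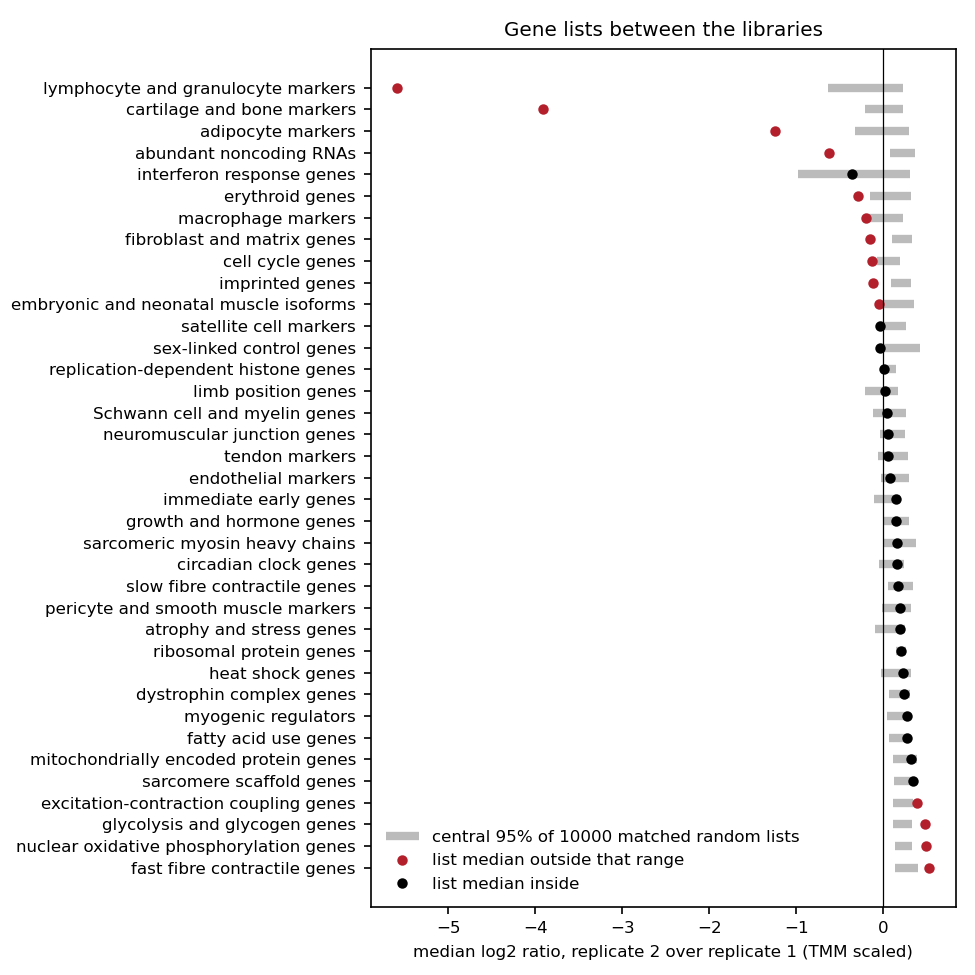
Median log2 ratio of replicate 2 over replicate 1 (x axis, TMM-scaled) for 37 gene lists (y axis); grey bars span the central 95% of 10000 random lists of matched expression, and red points are the 14 medians outside it. Cartilage and bone markers lie at -3.91 and fast contractile genes at 0.52.

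Short RNAs were the genes on which the RSEM-format and kallisto-format tables differed most. Rn7sk stood at TPM 27122 against 0.276, and Rmrp, Gm23444, Gm23472, Gm47302, Gm24950 and mt-Atp8 were at 0 in the kallisto-format tables with RSEM-format TPMs of 3261, 2371, 2371, 2106, 1283 and 3429. In the other direction Gm28439, Gm47283, Gm10156, Gm47673 and Prn were at 0 in the RSEM-format tables, with kallisto-format TPMs of 274, 67.1, 55.6, 29.0 and 23.7, and Gm7206 stood at 0.0150 against 107. Of 7435 genes at mean TPM 10 or more by either tool, 816 differed at least 2-fold the same way in both libraries, 576 higher by kallisto and 240 by RSEM; 93 of the latter were small noncoding RNAs and 117 pseudogenes. Nuclear protein coding genes had a median log2 ratio of kallisto over RSEM of 0.59 in replicate 1 and 0.52 in replicate 2. With ratios centred on that median, a choice made after seeing the data, 114 and 275 genes differed. Across genes, Pearson's r between the tools was 0.854 and 0.860 in the 2 libraries. Of the spike-ins with at least 100 counts in both libraries, 31 in all, those shorter than 600 nucleotides had a median kallisto over RSEM count ratio of 0.489 in replicate 1 and 0.501 in replicate 2, and those of 1000 or more had 0.789 and 0.790.

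**Figure D5:**
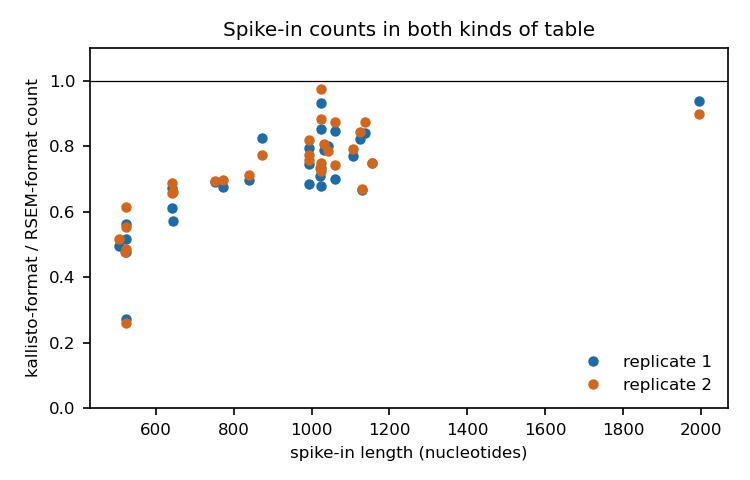
Ratio of kallisto-format to RSEM-format counts (y axis) against length in nucleotides (x axis) for 31 ERCC spike-ins with at least 100 counts, 1 point per library. The 6 shorter than 600 nucleotides have median ratios of 0.489 and 0.501.

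For 28 of 37 genes chosen for known muscle isoforms, both tools named the same leading transcript in both libraries. Tpm1-205 led alpha tropomyosin with 96.8% ± 0.883 of the gene's TPM by RSEM and 74.4% ± 0.834 by kallisto (SD, n = 2). Atp2a1-201 held 83.5% ± 0.819 and 87.2% ± 2.91, Ryr1-202 88.1% ± 4.32 and 78.0% ± 0.258, and Cacna1s-204 59.6% ± 2.14 and 86.3% ± 1.89. Ldb3-207 held 70.3% ± 0.653 and 66.9% ± 0.806, Nrap-202 72.1% ± 2.06 and 80.1% ± 2.20, Pdlim5-203 89.8% ± 2.13 and 75.6% ± 2.98, and Dmd-203 of dystrophin 64.8% ± 10.1 and 59.4% ± 3.30. The tools named different leading transcripts for Tnnt3, Tnnt1, Pkm, Myl1, Capzb and Trdn, so no leading form is given for these. Over 5201 genes with several transcripts and a mean TPM of at least 10, the tools agreed on the leading transcript in 72.2% and 73.4% of genes in the 2 libraries, RSEM gave the same one in both libraries for 91.6%, and kallisto for 86.6%.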

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

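No test in this part was chosen after a result was seen, since none was run. PhiX, a bacteriophage used as a sequencing control, had an expected count of 45 in replicate 1 and 1 in replicate 2. The first value is above the 3 counts that a count of 0 allows, in data outside the comparisons. The 26248 rows that carry a number and no gene name held 4.95 expected counts in replicate 1, over 5 rows, and 2 in replicate 2. Neither is weighed here.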

How the results depend on the processing

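The counts without listed bone and marrow genes, with centred ratios and with long genes only were chosen after the results were seen; the other alternatives were planned. Genes detected were 8093 at TPM 5. The replicate r was 0.951 with a pseudocount of 0.1 and 0.991 over all genes. The coefficient of variation was 0.233 with library totals, 0.157 at a mean count of 100 and 0.222 with kallisto-format counts. Genes that differed between replicates, 120 in the main setting, were 189 with library totals, 286 with spike-in scaling, 692 at a mean count of 20, 7452 with no count filter, 523 at 1.5-fold, 33 at 4-fold and 183 with kallisto-format counts. They were 102 without listed bone and marrow genes, within 1.5 times the main count. Looser filters and fold limits add genes by construction. Library totals and spike-in scaling lower every log2 ratio of replicate 2 over replicate 1, by 0.24 and 0.39, which moves their counts. The cause of the other changes was not tested.

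By kallisto-format TPM, expected counts and a nuclear protein coding denominator in turn, the share of fast contractile genes was 14.0%, 10.9% and 18.3%, of slow contractile genes 0.361%, 0.335% and 0.462%, of fibroblast and matrix genes 1.27%, 3.13% and 1.87%, and of mitochondrially encoded protein genes 5.19%, 2.65% and 7.65%. The last was 3.78% by posterior mean TPM. The denominator raises shares by construction, and the cause of the rest was not tested. Nuclear protein coding genes held 77.8% of counts and 75.6% of kallisto-format TPM, and small noncoding RNAs 5.32% and 0.0285%. Myh1 held 24.0% of myosin heavy chain TPM by kallisto-format values. By kallisto-format TPM and expected counts in turn, Myh6 held 0.128% and 0.0873%, and Myh7 1.24% and 1.26%. The shares of Myh4, Myh8 and Myh2 moved by less than 1 SD under each alternative.

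Genes that differed between the tools were 1863 at mean TPM 1, 367 at mean TPM 50, 314 at 4-fold, 401 by estimated counts, 389 with centred ratios and 400 with a length of at least 1000 nucleotides. Agreement on the leading transcript was 74.0% at mean TPM 1, 67.5% at mean TPM 50, and 82.4% where that transcript held 50% or more. Cox7a2 over Cox7a1 changed sign, to 0.31 by kallisto-format TPM and 0.22 by expected counts, and with spike-in scaling 21 of the 24 list medians above 0 turned negative, among lists outside the random range only that of excitation-contraction coupling genes, to -0.0105; the first cause was not tested, and the second is the shift that scaling gives every gene. The other 27 pairs kept their sign under each alternative. Of 183 list medians under alternatives, 169 stayed on the same side of the random range, 10 moved outside it and 3 inside. These 3 were macrophage markers at a mean count of 100 and with kallisto-format counts, and embryonic and neonatal isoforms against unmatched lists. Leaving out either replicate moved none of the counts of detected genes by over 1.5 times. With 2 libraries, a value from 1 of them always lies 0.71 SD from the mean, so leaving out a replicate cannot show that a mean is stable. For r and the coefficient of variation there is no replicate spread, and the limits used, 0.01 and 1.1-fold, were set after earlier numbers had been seen. With 2 libraries the depth limits single low genes, and the number of libraries limits every SD.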

Other observations

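Tests on connective tissue genes, a change limited to the Meg3 locus, small nuclear RNAs and spike-in counts were chosen after the result was seen. Those on further bone and marrow genes, further brain genes and further nuclear noncoding RNAs were fixed before these genes were looked at. In the bone list Mmp13 and Acp5 were exceptions, since both had already come up among the largest replicate differences. The medians of the immediate early, clock, atrophy and stress, and heat shock lists lay inside the random range. That of 16 immediate early genes was a log2 ratio of 0.15, or -0.25 with spike-in scaling, while Nr4a1 stood at 1.43 and Dusp1 at 0.87; with spike-in scaling these were 1.04 and 0.48. Of 16 clock genes, Per1 stood at 1.29, or 0.89 with spike-in scaling, and the median at 0.16, or -0.23. The atrophy genes Trim63 and Fbxo32, ubiquitin ligases of muscle wasting, stood at 0.78 and 0.81, or 0.39 and 0.42 with spike-in scaling, against Cdkn1a at -0.39. The 10 heat shock genes had a median of 0.22, or -0.17 with spike-in scaling. Of the 10 interferon response genes, 2 were detected and 1 was at 0 counts in both libraries.

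Of the neuron and axon genes, Syt1 had 75 and 5 counts in replicates 1 and 2, Snap25 36 and 1 and Tubb3 42 and 5, while Uchl1 had 209 and 192 and Nefh 11 and 14. A test planned for reads of a brain library was run but this pattern is not weighed further: of 18 further brain neuron and glia genes with at least 20 reads, 7, or 38.9%, were at least 4-fold higher in replicate 1, below the 50% set beforehand as speaking against such reads. Slc17a7 had 164 and 198 counts and Gad1 31 and 41. Camk2a, Aqp4 and Mapt, which the muscle expressed at TPM 27.6 or more in replicate 1, stood at log2 ratios of 0.33, 0.11 and 0.23, and at -0.06, -0.28 and -0.17 with spike-in scaling.

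Bone and marrow transcripts in replicate 1 may come from bone tissue taken with that muscle. Of 32 further bone cell, neutrophil precursor and erythroblast genes with at least 20 reads, 81.25% were at least 4-fold higher in replicate 1, above the 80% set beforehand by less than 1 gene, with 17 of 19 for bone cells, 5 of 6 for neutrophil precursors and 4 of 7 for erythroblasts; Mmp9 had 3676 and 69 counts. Without Mmp13 and Acp5, which had come up among the largest replicate differences before the test was run, 24 of 30 were, or 80%. More connective tissue of the muscle itself is argued against, since Col3a1, Dcn, Lum, Pdgfra, Mfap5 and Pi16 had a median fold of 1.00 between replicates 1 and 2, far below the 4-fold that explanation needs. These genes were picked from the fibroblast and matrix list after the result was seen, without Col1a1 and Col1a2, which were lower in replicate 2. Over all 23 members of that list the median log2 ratio was -0.15, also far from 4-fold. The replicate 2 library still held 145 counts of Dmp1 and 77 of Alpl, against 1224 and 579 in replicate 1. Ibsp and Bglap were at 0 counts there, against 1900 and 737. These genes do not give 1 common share, so bone tissue in replicate 2 was not shown and a smaller amount stays open. No other explanation was tested.

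Long noncoding RNAs of the nucleus were lower in replicate 2, with Miat at a log2 ratio of -1.88, Meg3 at -1.37 and Kcnq1ot1 at -0.90. Of 12 further noncoding RNAs with a mean count of at least 100, listed before their values were seen, 11 were lower. The median of the 12 was -0.53, or -0.40 with kallisto-format counts. Mir99ahg stood at -1.04, Tug1 at -0.02 and Gm20388 at 1.06. Gm20388 was at 11.3 with kallisto-format counts, so the size of its ratio is uncertain. The 12 RNAs were listed as nuclear, but their place in the cell was not measured. None lies in the imprinted Meg3, Rian and Mirg locus, so a change limited to that locus is argued against. Miat and Kcnq1ot1, also outside it, had been seen to be low before that test was chosen, so it added little. A lower amount of nuclear RNA in the replicate 2 library may be the source and stays open, since 15 small nuclear RNAs, entries with equal counts taken once, went both ways, 9 lower and 6 higher, with a median of -0.0445 and an SD of 0.809; Rn7sk stood at 0.04, Rpph1 at 0.37 and Gm23444 at 0.47. The SD rests on Gm24497 at -2.98 and is 0.281 without it, which would speak against this source. With spike-in scaling 14 of the 15 were lower, at a median of -0.44, and the median of the 12 further noncoding RNAs was -0.92. Since that scaling lowers every log2 ratio by 0.39, it leaves the gap between the 2 sets in place and cannot decide the question. Handling of the RNA and other differences between the muscles were not tested.

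Kallisto-format counts fell below RSEM-format counts for short transcripts, with a median ratio of 0 over 70 genes shorter than 300 nucleotides, 0.638 from 300 to 600 and 1.08 from 2000. Reads whose fragment would overrun the transcript end may be left out of the kallisto-format counts. Over 31 spike-ins, the ratio of counts and the ratio of effective lengths had a Spearman rho of 0.763 in replicate 1 and 0.769 in replicate 2. Both values lay between the bounds of 0.8 and 0.3 set for and against this explanation. The ratio of effective lengths rose steadily with spike-in length, so rho equals that of the count ratio with length itself. It cannot tell this explanation from any other loss at short lengths, and the explanation stays open. The rho values are across spike-ins of 2 libraries, and no biological explanation was tested.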
